A study of Arabidopsis thaliana with 18 samples.

How the data were processed

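Seedlings of Arabidopsis thaliana were grown for 7 days at 22 °C under days of 16 h light with nights of 8 h, and were either left at 22 °C or moved to 37 °C for 1 h before harvest, per the labels' protocols. Col-0 is the laboratory wild type. The label sant-null is the submitters' name for plants altered in SANT1/2/3/4, proteins with a SANT domain, and hda6 is a mutant of the histone deacetylase gene HDA6. Total RNA was extracted with TRIzol, and messenger RNA libraries were sequenced from paired ends. The 18 libraries form 6 groups of 3. The labels do not say whether the 3 libraries of a group came from separate plates or sowings, so p-values measure only the spread between these libraries, which may be technical.

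Per the submitters' processing notes, CASAVA, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.30.1 and the TAIR10 build were used. The role, order and settings of these tools are not given in the sources used here, nor is the handling of reads that match several places or of strand. Genes with near-identical copies, and genes that overlap others, are therefore uncertain. The authors deposited expression as FPKM (fragments per kilobase of gene and M fragments, where M stands for mega), with a single column per group, which holds the authors' mean of the group. FPKM values therefore carry no SD here. The authors also deposited 5 comparison tables, heat in Col-0 and each mutant against Col-0 at each temperature. In each, the authors' baseMean is a signal averaged over the libraries compared, and the deposited log2 fold change has a standard error beside it. The deposited Wald score equalled the log2 fold change divided by that error to within 1.34e-06. The deposited p-value was the 2-sided normal p of that score to within 5.00e-08. These tables listed 24615 genes for heat in Col-0, of which 23195 had an adjusted p.

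The design fixed before the data were examined was a limma fit to log2 FPKM of each library. That fit, its pseudocount, its replicate block, the removal of each library in turn, other splits of the libraries and estimated correlations between genes could not be fitted, because the FPKM columns hold a single value per group. The authors' deposited tables, planned as an alternative, were used as the main result, at an adjusted p under 0.05. The planned condition that named genes show no overlap between replicates could not be applied for the same reason. The remaining 6 comparisons were derived from the deposited log2 fold changes and standard errors with Wald tests and Benjamini-Hochberg adjustment. The interaction of a mutant and heat was the deposited log2 fold change at 37 °C minus that at 22 °C, whose libraries do not overlap. Heat within a mutant, and sant-null against hda6, combine tables that share Col-0 libraries. For these the squared errors of the mutant-against-Col-0 tables alone were summed. The error of heat in Col-0 was left out, because the Col-0 levels cancel in heat within a mutant. The sum is an upper bound and makes the tests conservative.

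The depth was estimated from the FPKM values, because a gene with a single read has a value set by its length and the library's total. The 18 totals recovered this way ranged from 38.1 to 53.6 M, and between 48.0% and 48.6% of each group's total was assigned to genes. That gives 18.4 to 25.9 M assigned fragments per library when the group's percentage is used for each of its libraries. Whether these totals count fragments or the 2 reads of each pair separately is not given in the sources used here, and in the latter case the assigned percentage would be about 2 times as high. On simulated changes with the errors of the real tables, the share of genes called at a log2 change of 1 was 85.7% for heat in Col-0 and 96.4% for sant-null against Col-0 at 22 °C. It was 95.9% for hda6 against Col-0 at 22 °C, 91.8% and 87.9% for sant-null and hda6 against Col-0 at 37 °C, and 88.2% and 80.4% for the sant-null and hda6 interactions. It was 77.6% and 85.5% for heat in sant-null and in hda6, and 87.3% and 69.6% for sant-null against hda6 at 22 °C and 37 °C. Each simulation changed 200 genes with a baseMean of at least 50. With so few changed genes the adjusted p is harder to reach than in real comparisons with many more calls, so the shares are likely too low for those.

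All 32548 genes of the FPKM table were matched by identifier to the RefSeq annotation of TAIR10.1, which was used for names, products, biotypes and neighbouring genes, with no coordinates printed. In total 17 gene lists with 299 entries were fixed before the data were examined. They cover small heat shock proteins, large heat shock chaperones and heat-induced genes, heat shock transcription factors, endoplasmic reticulum protein folding, oxidative stress, photosynthesis, abscisic acid and cold, defence, flowering time, the circadian clock, histone deacetylases, DNA methylation and silencing factors, loci silenced by DNA methylation with ONSEN copies, auxin response and warmth-induced growth, and markers of root tissue, seed storage and floral organs. Lists were tested against all other genes on the Wald scores with cameraPR in limma 3.58.1 under R 4.3.3, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A correlation of 0.05 was added after the data were seen. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

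Named genes were chosen by a rule set in advance. It took HDA6, up to 4 called members of each list with the largest absolute log2 fold change, or the member with the smallest p where none was called, and the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 1. Settings laid down in advance that could be run were all genes with a p instead of those with an adjusted p, FPKM as deposited in place of size factors, an absolute log2 fold change of at least 1 as well, and the heat response of Col-0 in place of that of the third genotype. Settings added after the data were seen were a mean FPKM of at least 1 in a compared group, an equal split of the variance between groups, and the correlation of 0.05. The FPKM scale differs from the deposited scale by a single offset per comparison, a shift of -1.01 for heat in Col-0, 0.09 and 0.04 for sant-null at 22 °C and 37 °C, and 0.05 and -6.38e-04 for hda6.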

Results

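Messenger RNA was measured in 7-day-old whole seedlings of Col-0, sant-null and hda6 at 22 °C and after 1 h at 37 °C, with 3 libraries in each of 6 groups. The stated purpose was to examine how SANT1/2/3/4 act on transcription at high temperature. The estimated depth was 18.4 to 25.9 M assigned fragments per library. FPKM values are the authors' group means, and the error given with each log2 fold change is its standard error.

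HDA6 (AT5G63110), the gene altered in hda6, had a similar transcript level in all genotypes. Its mean FPKM at 22 °C was 6.83 in Col-0, 6.94 in sant-null and 7.60 in hda6, and at 37 °C it was 3.96, 4.03 and 3.45. The authors' deposited table gave log2 fold changes of 0.10 ± 0.09 at 22 °C (adjusted p = 0.602) and -0.20 ± 0.13 at 37 °C (adjusted p = 0.351) in hda6 against Col-0. The authors' deposited table gave -0.07 ± 0.09 and -0.02 ± 0.12 for sant-null. The transcript level therefore does not check the hda6 label, and SANT1 to SANT4 carry no such names in the annotation used here and were not analysed individually.

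Heat in Col-0 raised the genes for heat shock chaperones and the transcription factors that control them. In the authors' deposited table the small heat shock proteins HSP17.7 (AT5G12030) and HSP23.6 (AT4G25200) rose by 11.03 ± 0.10 and 10.94 ± 0.20 on the log2 scale. The disaggregase HSP101 (AT1G74310) went from a mean FPKM of 5.09 to 2594, and the chaperone HSP70B (AT1G16030) from 4.01 to 2693. In the authors' deposited table the heat shock transcription factors HSFA2 (AT2G26150) and HSFA7B (AT3G63350) rose by 10.77 ± 0.08 and 10.45 ± 0.15. Among genes with a mean FPKM of at least 1, the largest rise in the authors' deposited table was that of AT1G21940, of unknown function, at 11.91 ± 0.44, and the largest falls included the mitogen-activated kinase kinase kinase gene MAPKKK14 (AT2G30040) at -4.97 ± 0.39 and OFP16 (AT2G32100) at -4.93 ± 0.62.

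Of 18 small heat shock protein genes in the authors' deposited table for heat in Col-0, 17 rose and 1 fell, with the same counts adjusted over the list alone. All 32 large chaperone and heat-induced genes rose, also adjusted over the list alone. Among 19 heat shock transcription factors 11 rose and 2 fell, and of 18 endoplasmic reticulum folding genes 15 rose and 0 fell. Adjusted over the list alone these were 11 and 2, and 15 and 1, and on the FPKM scale 10 and 5, and 10 and 6. The folding genes included the cofactor ERDJ3A (AT3G08970) at 8.68 ± 0.09 and the chaperone BIP1 (AT5G28540) at 4.24 ± 0.07 in the authors' deposited table. Of 15 abscisic acid and cold genes 10 rose and 0 fell, the same adjusted over the list alone (6 and 4 on the FPKM scale), with KIN1 (AT5G15960) at 3.10 ± 0.16 and the dehydrin COR47 (AT1G20440) at 2.56 ± 0.06 in the authors' deposited table. Of 12 oxidative stress genes 8 rose and 2 fell, the same adjusted over the list alone, led in the authors' deposited table by the zinc finger gene ZAT12 (AT5G59820) at 6.52 ± 0.12, while on the FPKM scale 5 were higher and 6 lower. In cameraPR the adjusted p was 1.6e-281, 3.9e-34, 4.5e-23, 0.00158 and 5.4e-05 for the small heat shock, transcription factor, folding, abscisic acid and oxidative stress lists, and 4.7e-228 for the large chaperones at a correlation of 0.05. On the FPKM scale the oxidative stress list had adjusted p = 0.0566.

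Of 26 photosynthesis genes in the authors' deposited table, 24 rose and 1 fell with heat, the same adjusted over the list alone, with a median of 0.57, but on the FPKM scale 0 were higher, 24 were lower and the median was -0.44. The cameraPR adjusted p for this list was 8.7e-05 with a direction of up, and 0.110 with a direction of down on the FPKM scale. The rubisco activase gene RCA (AT2G39730) was at 1.09 ± 0.05 in the authors' deposited table, against a mean FPKM of 3217 at 22 °C and 3411 at 37 °C. Root markers fell on either scale, 12 of 16 against 1 rise, the same adjusted over the list alone, with the proline-rich protein gene PRP1 (AT1G54970) at -2.79 ± 0.29 in the authors' deposited table. The cameraPR adjusted p for root markers was 0.0308, and 0.0971 at a correlation of 0.05. Among 22 auxin response genes 14 fell and 3 rose, the same adjusted over the list alone (21 and 1 on the FPKM scale), including SAUR20 (AT5G18020) at -3.75 ± 0.37 in the authors' deposited table, with a cameraPR adjusted p of 0.211.

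Among clock and histone deacetylase genes more rose than fell with heat in Col-0 on the deposited scale, and more fell than rose on the FPKM scale. Of 15 clock genes 8 rose and 2 fell (the same adjusted over the list alone), with RVE1 (AT5G17300) at 2.04 ± 0.09 in the authors' deposited table and adjusted p = 0.0222, or 0.0764 at a correlation of 0.05. On the FPKM scale 5 clock genes were higher and 7 lower, with adjusted p = 0.370. Of 17 histone deacetylase genes 7 rose and 0 fell (the same adjusted over the list alone), led in the authors' deposited table by HDA8 (AT1G08460) at 3.64 ± 0.08, while on the FPKM scale 2 were higher and 13 lower. Of 11 DNA methylation and silencing genes 3 rose and 4 fell, with 3 and 6 adjusted over the list alone and 0 and 11 on the FPKM scale, including the methyltransferase gene CMT2 (AT4G19020) at -1.26 ± 0.11 in the authors' deposited table. Defence genes rose in 5 and fell in 6 of 17 cases (5 and 7 adjusted over the list alone; 4 and 10 on the FPKM scale). Flowering genes rose in 3 and fell in 4 of 20 (3 and 3 adjusted over the list alone; 0 and 11 on the FPKM scale). Flowering genes had a median of 0.16 and a cameraPR direction of down at adjusted p = 0.367, and on the FPKM scale their median was -0.85. The methylation-silenced list had 2 genes tested and 0 called. Of 8 seed storage genes 2 rose and 0 fell (1 and 0 adjusted over the list alone; 1 and 2 on the FPKM scale), with a median of 1.60 and a cameraPR direction of down at adjusted p = 0.944. Of 6 floral organ genes 1 rose and 0 fell (the same adjusted over the list alone; 0 and 1 on the FPKM scale), with a median of 0.39, a direction of down at adjusted p = 0.944, and -0.62 on the FPKM scale.

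In all, 6979 genes rose and 6930 fell among 23195 tested in the authors' deposited table, and 2043 and 3919 of these changed at least 2-fold. The share of calls that were higher was 50.2%, and 7.94% on the FPKM scale, where every gene is shifted by -1.01. The 50 genes of the small and large heat shock lists held 0.572% of assigned fragments in Col-0 at 22 °C and 22.2% at 37 °C.

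The heat response within each mutant, derived from the authors' deposited tables, had the same leading groups. In sant-null 17 of 18 small heat shock protein genes rose and 1 fell, and 31 of 31 large chaperone genes rose, with the same counts adjusted over the list alone. In hda6 the counts were 17 of 18 with 1 fall, and 32 of 32, again the same adjusted over the list alone. In sant-null 6075 genes rose and 5066 fell of 21295 tested, and in hda6 5913 rose and 5159 fell of 20481. The higher share was 54.5% and 53.4%, and 6.59% and 5.95% on the FPKM scale. Of the genes tested in each pair, 5804 rose and 4762 fell in Col-0 and sant-null alike, against 1943 and 1594 for independent lists. For Col-0 and hda6 these were 5613 and 4681 against 1964 and 1648. Across genes with FPKM of at least 1, which are not independent replicates, Pearson's r between the Col-0 response and that of the mutant was 0.963 and 0.954.

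In sant-null at 22 °C, transcripts of small heat shock proteins and large chaperones were lower than in Col-0, and REM22 and AT5G66150, which had little transcript in Col-0, were higher. HSP21 (AT4G27670), a chloroplast small heat shock protein, was in the authors' deposited table at -4.81 ± 0.54, HSP22.0 (AT4G10250) at -4.63 ± 0.52 and HSP70B at -1.97 ± 0.14. Their mean FPKM values were low in Col-0 as well, at 2.05, 1.92 and 4.01. The B3-domain gene REM22 (AT3G17010) was in the authors' deposited table at 8.99 ± 1.03 and AT5G66150, a glycosyl hydrolase gene, at 7.01 ± 0.39, with FPKM of 6.04 and 4.33 in sant-null. The phosphatidylinositol kinase-like gene AT5G24240 was at -4.29 ± 0.17 in the authors' deposited table, with FPKM of 6.64 in Col-0 and 0.361 in sant-null.

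By list, 12 of 18 small heat shock protein genes were lower and 2 higher in the authors' deposited table for sant-null at 22 °C (13 and 2 adjusted over the list alone), and 19 of 31 large chaperone genes were lower and 2 higher (21 and 2). The cameraPR adjusted p was 5.8e-12 and 4.0e-13, and the list medians were -1.335 and -0.29. In 18 strongly heat-induced genes the excess of Col-0 over the mean of both mutants at 22 °C had a median of 0.1% of the Col-0 level at 37 °C. These genes had an FPKM above 100 in Col-0 at 37 °C. In each mutant their level at 22 °C was under 0.1% of that at 37 °C. The choice therefore uses the mutant levels at 22 °C, and 10 of these genes are in the small heat shock protein list. Whether the excess reflects heated material in the Col-0 libraries at 22 °C stays open and is taken up below. Of 26 photosynthesis genes 16 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 5.8e-12), with LHCB1.4 (AT2G34430), a light-harvesting protein gene, at -0.44 ± 0.05 in the authors' deposited table, and on the FPKM scale 9 were lower and 2 higher. Of 12 oxidative stress genes 5 fell and 2 rose (the same adjusted over the list alone; adjusted p = 4.7e-05), with the catalase gene CAT3 (AT1G20620) at -0.48 ± 0.03 in the authors' deposited table. Of 18 folding genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00237), and on the FPKM scale 2 fell and 2 rose.

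Flowering repressors changed in either direction in sant-null at 22 °C, and the lists of flowering and deacetylase genes were not called. MAF4 (AT5G65070) was at 2.18 ± 0.21 in the authors' deposited table, FLC (AT5G10140) at 0.84 ± 0.25, TEM2 (AT1G68840) at -0.71 ± 0.05 and the deacetylase gene HDA18 (AT5G61070) at 3.16 ± 0.29. Of 20 flowering genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.519), and of 18 deacetylase genes 2 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.725, with a median of -0.0036 and a direction of up; 2 and 0 on the FPKM scale). Of 9 seed storage genes 3 rose and 0 fell (the same adjusted over the list alone; adjusted p = 0.0113, and 0.0570 on the FPKM scale), with the cruciferin gene CRA1 (AT5G44120) at 5.38 ± 0.51 in the authors' deposited table and an FPKM of 1.67 in sant-null. Of 15 abscisic acid and cold genes 5 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.652, with a median of -0.04 and a direction of up; 5 and 3 on the FPKM scale), with COR15A (AT2G42540) at 2.42 ± 0.25 in the authors' deposited table. Counting all genes in the authors' deposited table, 2059 genes were higher and 2096 lower of 23342, and 926 and 71 at least 2-fold. The higher share was 49.6%, and 77.7% on the FPKM scale, but 39.97% among genes with a mean FPKM of at least 1 in a compared group.

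In sant-null at 37 °C heat shock genes differed less from Col-0 than at 22 °C, while MAF4, FLC and HDA18 were again higher. HSP21 was in the authors' deposited table at 0.89 ± 0.04 and HSP14.7 (AT5G47600) at 3.34 ± 0.27, with FPKM of 1996 and 6.36 in sant-null against 1045 and 0.608 in Col-0. MAF4, FLC and HDA18 were in the authors' deposited table at 2.18 ± 0.28, 1.23 ± 0.26 and 3.15 ± 0.45, and AT5G24240 at -5.31 ± 0.28. REM22 was listed at 0 in Col-0, with an FPKM of 2.34 in sant-null.

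By list at 37 °C, 6 of 18 small heat shock protein genes rose and 1 fell in sant-null in the authors' deposited table (8 and 1 adjusted over the list alone; 9 and 0 on the FPKM scale; adjusted p = 8.1e-12). The median of this list was only 0.09, so HSP21 was far above the typical member. Of 32 large chaperone genes 2 rose and 13 fell (2 and 14 adjusted over the list alone; adjusted p = 2.1e-07), with HSP90.3 (AT5G56010) at -0.32 ± 0.05 in the authors' deposited table. Of 18 folding genes 0 rose and 5 fell (0 and 6 adjusted over the list alone; adjusted p = 7.3e-05), with the chaperone BIP2 (AT5G42020) at -0.39 ± 0.05 in the authors' deposited table. Of 26 photosynthesis genes 2 rose and 11 fell (2 and 14 adjusted over the list alone; 2 and 7 on the FPKM scale; adjusted p = 2.1e-07). Of 12 oxidative stress genes 2 rose and 5 fell (2 and 6 adjusted over the list alone; adjusted p = 3.8e-05), with the superoxide dismutase gene CSD2 (AT2G28190) at 0.68 ± 0.09 and ZAT7 (AT3G46090) at -0.86 ± 0.11 in the authors' deposited table. Counting all genes in the authors' deposited table, 1026 genes were higher and 880 lower of 21736, and 502 and 60 at least 2-fold. The higher share was 53.8%, and 68.1% on the FPKM scale, but 43.96% among genes with a mean FPKM of at least 1 in a compared group.

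In hda6 at 22 °C, QQS and several genes listed at 0 in Col-0 were higher. Transcripts of most small heat shock proteins and some large chaperones were lower. AT5G41660, AT2G03965 and the repressor gene OFP9 (AT4G04030) were listed at 0 in Col-0 at 22 °C, with FPKM of 23.46, 14.08 and 10.02 in hda6. The orphan gene QQS (AT3G30720) was in the authors' deposited table at 5.37 ± 0.23. The DNA demethylase gene ROS1 (AT2G36490) was at -1.17 ± 0.10 and the histone demethylase gene IBM1 (AT3G07610) at -0.60 ± 0.12 in the authors' deposited table. HSP22.0, HSP21 and HSP70B were at -6.42 ± 0.87, -6.04 ± 0.77 and -2.13 ± 0.14 in the authors' deposited table. Their mean FPKM in hda6 was 0.0245, 0.0302 and 0.951, so the sizes for HSP22.0 and HSP21 rest on levels near the floor.

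By list, 14 of 18 small heat shock protein genes were lower and 1 higher in hda6 at 22 °C in the authors' deposited table. Adjusted over the list alone the counts were the same, and the cameraPR adjusted p was 3.3e-24. The Col-0 excess given above was measured in strongly heat-induced genes, of which 10 are in this list. It was taken against the mean of both mutants. Of 32 large chaperone genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; 9 and 0 on the FPKM scale; adjusted p = 7.3e-13). The median of the large chaperone list was -0.17. Of 26 photosynthesis genes 23 fell and 0 rose (the same adjusted over the list alone; 16 and 0 on the FPKM scale; adjusted p = 8.6e-26), with LHCB1.4 at -0.41 ± 0.04 in the authors' deposited table. The median of the photosynthesis list was -0.17, and -0.12 on the FPKM scale. Root markers rose in 9 of 16 cases and fell in 0 (9 and 2 adjusted over the list alone; adjusted p = 0.00202), with PRP3 (AT3G62680) at 0.57 ± 0.11 in the authors' deposited table. Of 11 DNA methylation and silencing genes 2 fell and 0 rose (the same adjusted over the list alone; adjusted p = 0.00245). Of 3 methylation-silenced genes tested 2 rose (3 adjusted over the list alone; adjusted p = 1.0e-16). Of 20 flowering genes 3 rose and 3 fell (3 and 5 adjusted over the list alone; 3 and 1 on the FPKM scale; adjusted p = 0.780), with MAF4 at 1.60 ± 0.23 and FLC at 0.76 ± 0.25 in the authors' deposited table. Of 19 defence genes 2 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.780), with PR1 (AT2G14610) at 6.84 ± 1.06 in the authors' deposited table and an FPKM of 1.85 in hda6. Over all genes in the authors' deposited table, 1430 genes were higher and 1056 lower of 23447, and 578 and 36 at least 2-fold. The higher share was 57.5%, and 77.2% on the FPKM scale, but 49.45% among genes with a mean FPKM of at least 1 in a compared group.

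In hda6 at 37 °C, genes for protein folding in the endoplasmic reticulum were lower than in Col-0. BIP2, the calreticulin gene CRT1 (AT1G56340) and the calnexin gene CNX1 (AT5G61790) were in the authors' deposited table at -0.63 ± 0.04, -0.49 ± 0.05 and -0.48 ± 0.04. The B-box gene BBX18 (AT2G21320) was at -3.41 ± 0.12 and the abscisic acid hydroxylase gene CYP707A4 (AT3G19270) at -2.06 ± 0.19 in the authors' deposited table, with FPKM of 2.04 and 0.812 in hda6 against 21.7 and 3.38 in Col-0. QQS was in the authors' deposited table at 5.78 ± 0.45 and ROS1 at -1.18 ± 0.15. AT1G32010 was listed at 0 in Col-0, with an FPKM of 22.0 in hda6.

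Of 18 folding genes 10 fell and 0 rose in hda6 at 37 °C in the authors' deposited table (11 and 0 adjusted over the list alone; adjusted p = 6.2e-12). Of 32 large chaperone genes 19 fell and 3 rose (19 and 4 adjusted over the list alone; adjusted p = 6.1e-13), with HSC70-2 (AT5G02490) at -0.73 ± 0.06 in the authors' deposited table. Small heat shock protein genes rose in 9 of 18 cases and fell in 0 (10 and 0 adjusted over the list alone; adjusted p = 3.4e-06), with HSP21 at 0.40 ± 0.04 in the authors' deposited table. The median of this list was only 0.11. Of 14 abscisic acid and cold genes 2 rose and 7 fell (2 and 8 adjusted over the list alone; adjusted p = 0.00189), with KIN1 at -1.06 ± 0.17 in the authors' deposited table. Of 15 root markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.00398). Of 15 clock genes 2 rose and 5 fell (4 and 7 adjusted over the list alone), with adjusted p = 0.0454, and 0.122 at a correlation of 0.05. Of 18 heat shock transcription factors 1 rose and 5 fell (2 and 5 adjusted over the list alone), with adjusted p = 0.0229, and 0.0885 at a correlation of 0.05. Over all genes in the authors' deposited table, 1884 genes were higher and 1957 lower of 20790, and 412 and 207 at least 2-fold.

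**Figure D1:**
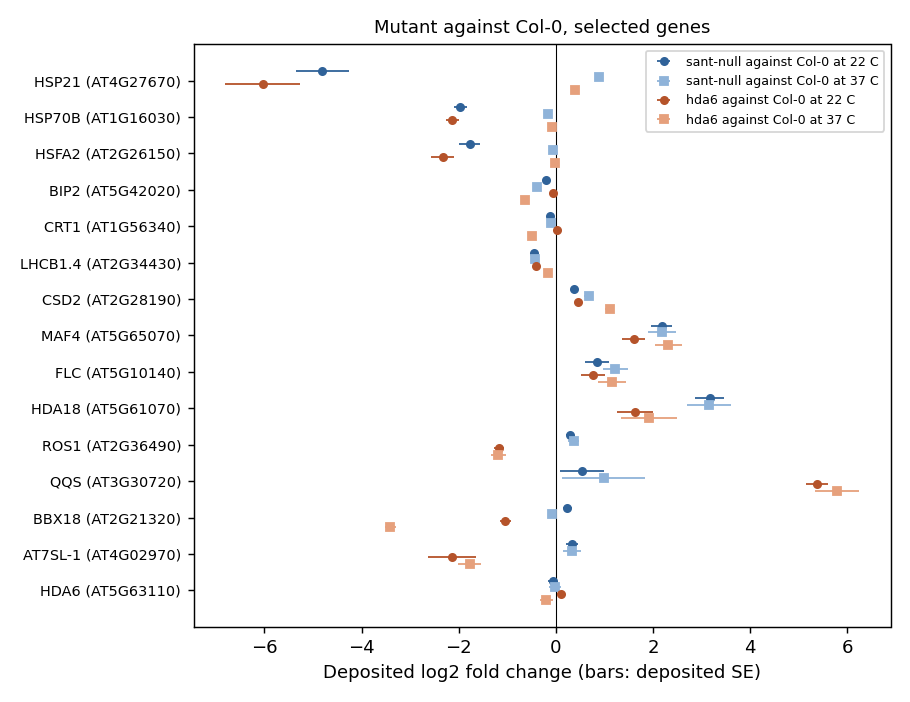
Log2 fold changes of 15 genes in each mutant against Col-0 at 22 °C and 37 °C, from the authors' deposited tables; points are the deposited values, horizontal bars their standard errors, and the axis is in log2 units. HSP21 moves from -4.81 and -6.04 at 22 °C to 0.89 and 0.40 at 37 °C in sant-null and hda6, QQS lies at 5.37 and 5.78 in hda6, and HDA6 lies near 0, where the sign of its sant-null values flips on the FPKM scale.

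The genes called in sant-null and in hda6 overlapped. At 22 °C 675 genes were higher in each mutant, against 109.7 for independent lists, and 615 were lower, against 96.7. At 37 °C 466 were higher, against 82.1, and 507 lower, against 83.5. Opposite calls numbered 13 and 36 at 22 °C and 47 and 34 at 37 °C. Across genes with FPKM of at least 1, Pearson's r between the effects was 0.549 at 22 °C and 0.590 at 37 °C, and Spearman's rho was 0.519 and 0.546. In 100 simulations of unchanged groups against shared Col-0 libraries, the mean r was 0.413 and 0.436 and the mean number of shared calls was 0. With no real change in any group hardly any gene can be called, so that 0 does not bear on the shared calls observed. The observed covariance was 0.129 and 0.146, against 0.0175 and 0.0368 simulated. Observed minus simulated covariance was 0.112 and 0.109, with the Col-0 variance of the simulation taken from the deposited errors. For the shared calls, part of the excess over independent lists may come from the shared controls, whose libraries could not be split here.

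Set against each other, the mutants differed at QQS, ROS1 and several other genes. QQS was at -4.83 ± 0.50 at 22 °C and -4.80 ± 0.97 at 37 °C in sant-null against hda6, computed from the authors' deposited tables. AT5G03090 had an FPKM of 0.469 in sant-null and 167 in hda6 at 37 °C (-8.54 ± 0.64). CRA1 was at 5.93 ± 1.33 at 22 °C, and BBX18 and the receptor-like gene RLP21 (AT2G25470) were at 3.32 ± 0.14 and 2.23 ± 0.14 at 37 °C. ROS1 was at 1.46 ± 0.13 and 1.55 ± 0.20. In sant-null 247 genes were higher and 459 lower of 22898 at 22 °C, and 503 and 419 of 20614 at 37 °C, with the conservative error. The higher share was 35.0% and 54.6%, and 48.0% and 67.5% on the FPKM scale.

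The interaction asked whether heat changed a transcript differently in a mutant than in Col-0. In sant-null it was 5.70 ± 0.54 for HSP21, 4.95 ± 0.52 for HSP22.0 and 1.81 ± 0.14 for HSP70B, computed from the authors' deposited tables, and their levels at 22 °C set most of these values. Negative interactions included CRA1 at -6.49 ± 0.85, the squalene epoxidase gene SQE2 (AT2G22830) at -1.76 ± 0.25 and the clock gene LNK2 (AT3G54500) at -0.34 ± 0.07. Of 18 small heat shock protein genes 10 were higher and 0 lower (14 and 1 adjusted over the list alone, with a cameraPR adjusted p of 3.4e-57). The Col-0 excess at 22 °C of 0.1% of the level at 37 °C was measured in strongly heat-induced genes, of which 10 are in this list. Heated material in the Col-0 libraries at 22 °C stays open as a source of this excess. In total 117 genes had a higher and 80 a lower interaction of 21392. Higher values made up 59.4% of calls, and 38.7% on the FPKM scale.

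In hda6 the interaction was 6.43 ± 0.77 for HSP21 and 6.65 ± 0.87 for HSP22.0, computed from the authors' deposited tables, and -2.37 ± 0.17 for BBX18, -0.57 ± 0.06 for BIP2 and -0.52 ± 0.07 for CRT1. For HSP21 and HSP22.0 the hda6 levels at 22 °C, with FPKM of 0.0302 and 0.0245, set most of these values. Of 18 small heat shock protein genes 13 were higher and 0 lower (15 and 0 adjusted over the list alone, with a cameraPR adjusted p of 1.6e-47). The Col-0 excess of 0.1% was again that of the strongly heat-induced genes, of which 10 are in this list. Of 18 folding genes 7 were lower and 0 higher (8 and 1 adjusted over the list alone; adjusted p = 1.3e-10). Of 26 photosynthesis genes 17 were higher and 0 lower (23 and 0 adjusted over the list alone; 10 and 0 on the FPKM scale; adjusted p = 3.5e-25). The iron transporter gene IRT1 (AT4G19690) was at 0.67 ± 0.11 and the clock gene PRR9 (AT2G46790) at -0.58 ± 0.11. In total 465 genes had a higher and 683 a lower interaction of 20598. Higher values made up 40.5% of calls, and 22.3% on the FPKM scale.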

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

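The interaction tests were set before the data were examined, for a fit that could not be made, and the tests of explanations in this part were chosen only after the results they bear on had been seen. The results here are differences between a mutant's heat response and that of Col-0. In sant-null 117 genes had a higher and 80 a lower interaction, and in hda6 465 and 683. The median interaction in sant-null was 1.48 for small heat shock proteins, 0.12 for large chaperones, 0.11 for heat shock transcription factors, 0.11 for oxidative stress, 0.0377 for photosynthesis, -0.10 for the clock and -1.69 for seed storage genes. Few single genes were called outside the small heat shock list: 4 of 31 large chaperone and 3 of 19 transcription factor genes were higher. Among oxidative stress genes 0 of 12 were called, and 0 of 26 for photosynthesis. In the clock list 1 of 15 was lower, and among seed storage genes 1 of 6, CRA1. On the FPKM scale the photosynthesis median was -0.0074, with adjusted p = 0.468. In hda6 the median interaction was 2.42 for small heat shock proteins, -0.11 for endoplasmic reticulum folding, 0.0042 for oxidative stress, 0.22 for photosynthesis and -0.21 for the clock. There 2 of 12 oxidative stress genes were higher and 0 lower, and of 15 clock genes 1 was higher and 5 were lower. On the FPKM scale the hda6 oxidative stress median was -0.05, with adjusted p = 0.138. At a correlation of 0.05 the hda6 lists for oxidative stress and the clock had adjusted p = 0.131 and 0.0634.

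The positive interactions of small heat shock protein genes rest on their low level in both mutants at 22 °C, where Col-0 is higher. The FPKM scale adds only 0.09 to every gene of sant-null at 22 °C. The list median there, -1.25, could therefore not come near 0 and does not test scaling. A single scaling factor would move all genes alike, whereas this list lay below the other genes on the deposited scale (cameraPR adjusted p = 5.8e-12). A common factor on basal transcription would lower moderately and strongly heat-induced genes alike. Genes were split by the Col-0 ratio of 22 °C to 37 °C, so that no mutant value entered the choice. The sant-null median was -0.24 for the 23 less induced genes and -2.35 for the 23 more induced ones. The difference was 2.11, with a 95% bootstrap interval over genes of 1.41 to 3.36. This argues against an equal factor on these genes in the group means. The interval holds no spread between libraries, and heat-induced genes may vary together. Carry-over would mean a fixed share of heated material in the Col-0 libraries at 22 °C. It would make the ratio of 22 °C to 37 °C similar across genes in Col-0. The SD of that ratio over the 18 strongly induced genes was 0.456 in log2 units in Col-0. It was 1.29 in sant-null and 1.62 in hda6 over the 16 above 0, where levels are lower and counting noise was not separated. Unlike the sets split by the Col-0 ratio, these 18 genes were chosen by a ratio under 0.1% in both mutants. That caps the mutant ratios, so the SDs do not decide on carry-over. Carry-over stays open. The median Col-0 excess was 0.0664% of the 37 °C level in 24 intermediate genes and 0.1% in the 18 strongly induced genes. Their ratio was 0.664, with an interval over genes of 0.397 to 0.996, which spans the lower bound of 0.5 set for equal shares. Intermediate genes had ratios from 0.1% to under 1% in both mutants. The mutant levels at 22 °C thus enter both the choice and the excess, and the interval holds no spread between libraries. Carry-over cannot be told apart from a mutant effect on the most strongly induced genes, which was not tested. All shares were taken of the Col-0 level at 37 °C, so heated material of a mutant as the source was not tested either.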

How the results depend on the processing

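The FPKM scale, all genes with a p, the 2-fold limit and the Col-0 heat response were planned, and the FPKM minimum of 1, the equal variance split and the correlation of 0.05 were chosen after the data were seen. No paired analysis was possible because the columns carry a single value per group and no replicate number. The planned limma fit, pseudocount, leave-one-out fits, fits to the compared groups and estimated correlation were not run for the same reason. With all genes that have a p, or only those with a mean FPKM of at least 1, each of the 24 main counts stayed within 1.5 times its main value. The balance of calls still moved with the FPKM minimum. The higher share was then 39.97% for sant-null and 49.45% for hda6 at 22 °C, and 43.96% and 48.12% at 37 °C. For heat in Col-0 it rose to 53.74%. In the simulations small changes were often missed: a log2 change of 0.5 was called in 60.3% of cases for heat in Col-0 and 35.4% for sant-null against hda6 at 37 °C. Only 200 genes were changed in each, whereas 13909 of 23195 were called for heat in Col-0. The adjusted p is harder to reach with few changed genes, so these shares are likely too low for comparisons with many calls.

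Requiring a 2-fold change as well gave these higher and lower counts, by construction smaller: 2043 and 3919 for heat in Col-0, 1785 and 3043 in sant-null and 1848 and 3104 in hda6. For sant-null against Col-0 it gave 926 and 71 at 22 °C and 502 and 60 at 37 °C, for hda6 578 and 36, and 412 and 207. For sant-null against hda6 it gave 68 and 69 at 22 °C and 89 and 59 at 37 °C. Interactions numbered 26 and 16 in sant-null and 27 and 103 in hda6, and the shared calls of both mutants fell to 270 at 22 °C and 160 at 37 °C.

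On the FPKM scale, which shifts every gene of a comparison by its offset, 1450 genes were higher and 16824 lower with heat in Col-0, 1080 and 15309 in sant-null, and 935 and 14775 in hda6. Lower counts became 867 for sant-null and 533 for hda6 at 22 °C, and 577 for sant-null at 37 °C. Higher interactions became 75 in sant-null and 246 in hda6. The cameraPR direction reversed for the photosynthesis list with heat in Col-0 (a net count of -24), and net counts changed sign for oxidative stress (-1), the clock (-2), deacetylases (2 higher, 13 lower), seed storage (1 and 2) and floral genes (0 and 1). Signs reversed for RBCS3B (-0.24) and HDA6 (-0.79) with heat, and HDA6 in sant-null (0.0224 at 22 °C and 0.0249 at 37 °C). With the equal variance split, sant-null against hda6 gave 996 and 1331 calls at 22 °C and 1346 and 1170 at 37 °C, because that error is smaller. Taking heat from Col-0, whose libraries also enter the mutant effect, the correlation across genes of heat and mutant effect at 37 °C was -0.0489 for sant-null and -0.0672 for hda6, against 0.0391 and 2.63e-04. At 22 °C it was -0.0103 and -0.00993, against -0.0669 and -0.0942 with heat from the other mutant.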

Other observations

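The tests and gene sets in this part were chosen after the data were seen. Genes next to the 8 ONSEN loci of the fixed list, a heat-activated retrotransposon family, were examined in the mutants. Of 15 such neighbours in the FPKM table, 10 rose at least 2-fold with heat in Col-0. At 37 °C 6 of these 10 were higher and 0 lower in hda6 against Col-0 (median 0.63), while in sant-null 0 were higher and 4 lower (median -0.43). In sant-null against hda6 0 were higher and 6 lower (median -1.35). AT1G21940 had an FPKM of 269.9 in Col-0, 116.5 in sant-null and 315.5 in hda6, and AT1G11270 had 43.05, 28.74 and 71.86. Against 100000 random lists of other heat-induced genes, the 2-sided permutation p was 5.0e-05 for hda6, 0.0066 for sant-null and 1.0e-05 for sant-null against hda6, the last being the smallest these lists can give. These p-values treat neighbours as independent genes, although all flank copies of a single family and some share a locus. They measure no spread between libraries. AT1G21950, AT1G48700 and AT3G32420 were also low in Col-0 at 37 °C, with FPKM of 0.319, 0.115 and 0.255. How reads from the repeated element were counted is not given in the sources used here.

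Gene families named by the annotation's product descriptions added further groups. In sant-null at 22 °C 15 of 34 AP2/B3-like transcription factor genes were higher and 0 lower in the authors' deposited table (median 1.07; cameraPR adjusted p = 6.6e-06 over 150 families, and 0.0157 at a correlation of 0.05). In hda6 at 22 °C 20 of 58 peroxidase genes were higher and 3 lower in the authors' deposited table (median 0.24; adjusted p = 2.9e-05, and 0.0404), beside 9 of 16 root markers higher and 23 of 26 photosynthesis genes lower. With heat in Col-0, 20 of 22 leucine-rich receptor-like kinase genes fell and 1 rose in the authors' deposited table (median -1.58; adjusted p = 7.0e-06, and 0.00302), and 21 of 30 histone genes fell and 2 rose (median -1.52; adjusted p = 8.2e-04, and 0.112 at a correlation of 0.05).

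Many genes that were at least 2-fold higher in a mutant were expressed at a low level. Of the 926 in sant-null and 578 in hda6 at 22 °C, 318 and 230 reached an FPKM of 1 in the mutant, and 37 and 80 were noncoding RNA genes. Reads from genomic DNA would lift silent genes alike: a rise by the median of those of these genes below 1 FPKM in Col-0 at 22 °C, 0.442 and 0.544 FPKM, would put 99.8% and 99.9% of the 7933 genes listed at 0 in both Col-0 groups above 0, whereas 12.3% and 13.9% were above 0. Deeper libraries are excluded, since the summed depth was 0.832 of that of Col-0 in sant-null and 0.886 in hda6. A candidate explanation for hda6, as a hypothesis, is loss of silencing near annotated pseudogenes. Among genes below 1 FPKM in Col-0 at 22 °C, 314 were at least 2-fold higher in hda6 alone and 618 in sant-null alone. Such a neighbour was found for 42.0% and 8.74% of these, an odds ratio of 7.58 (Fisher's exact test, 2-sided p = 1.0e-31). Among the genes not called 2-fold higher in hda6 the share was 9.72%. The test treats genes as independent, although adjacent genes can flank the same pseudogene. It measures no spread between libraries. Reads shared with near-identical copies were not tested.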
